A study of Rattus norvegicus with 6 samples.

How the data were processed

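Gene expression was measured by RNA-seq of mRNA-enriched RNA from 6 libraries, 3 control and 3 progesterone, of cultured postnatal day 7 rat cardiomyocytes. The libraries were grouped by their titles, and the labels speak of 3 biological replicates per group. Libraries were made with the TruSeq RNA kit, per the labels' protocols, whose strand setting is not given in the sources used here. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8, a mouse build, although the rows carry rat Ensembl gene identifiers. The rat build, annotation and read counter behind the values are not given in the sources used here. The authors deposited raw counts per gene, as whole numbers, and FPKM values per gene, scaled by gene length and library total. In the FPKM values the authors deposited, the divisor implied by counts and gene lengths was a single number per library and within 1.57% of the count total.

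The table holds 33565 rows, of which 682 are assembled loci without a gene name, and 254 rows with a clone name took their symbol through the NCBI gene accession in their description (RefSeq annotation of GRCr8, used for names alone). Assembled loci took 0.889% of the control and 0.844% of the progesterone counts, and 268 of the 515 tested changed. Where several rows had a symbol, the row with the highest count kept it. Coordinates are those of the table, for a rat build that is not named.

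Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling, robust glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment at 0.05). TMM factors ran from 0.984 to 1.01, and the biological coefficient of variation was 9.04%. CPM values are scaled by TMM and given as mean ± SD over 3 libraries. The SE of a log2 fold change was derived from the F statistic. Folds are 2 to the power of the fitted log2 fold change. Where a group had no count, the fold was computed against 3 counts over the group, and with 1 to 3 counts a ratio of pooled counts with an exact 95% binomial interval was used.

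The gene lists, the named-gene rule, the test and the alternatives not marked as added were set before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 over lists of at least 5 tested members, 34 in number. Of these, 14 were called, 11 higher and 3 lower. The calls of 2, the interferon-stimulated and the inflammatory list, hold with an estimated correlation. Adjusted over the list alone, the counts of changed members equal those over all genes tested except where given. The named genes are the 12 largest and 12 smallest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 1 CPM and groups that do not overlap, skipping rows without a symbol. To these were added a fixed set of YAP, steroid receptor, cell-cycle and cardiac genes, and up to 4 members per list with the smallest adjusted p.

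Replicates were compared before they were averaged. Pearson correlations of log2 CPM were 0.988 to 0.990 within groups and 0.905 to 0.914 between groups, and the first principal component, with 85.1% of the variance, separated the groups. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom 5.57 to 9.79), so none was counted as a duplicate. Counts were simulated for this comparison with 14743 genes, of which 50 changed at each fold. The test recovered 50% of genes changed 1.25-fold, 60% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, with 4 false calls among 154.

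Alternatives were RLE, upper quartile and library size scaling, no filter and a filter of 1 CPM in 3 libraries, each replicate left out in turn, the replicate number as a block, DESeq2 1.42.0, and limma on log2(FPKM + 1) and log2(FPKM + 0.1). List tests were also run with an estimated correlation and with fry. An alternative without 579 genes (mitochondrial genes and genes lower by 4-fold or more) and 5 further gene lists were chosen after seeing the data.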

Results

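Primary cardiomyocytes from 7-day-old Sprague-Dawley rats were grown in medium with 10% fetal bovine serum and exposed for 24 h to vehicle or to 100 nM progesterone, a steroid hormone that acts through nuclear and membrane receptors. mRNA-enriched RNA was sequenced from 3 control and 3 progesterone samples, which the labels call biological replicates. The libraries held between 21156793 and 25376220 counts. Whether the replicates came from separate animals or separate cultures is not given in the sources used here, so the p-values measure the spread between these samples, which may be technical. The series title names YAP, a transcriptional coactivator of the Hippo pathway, together with cardiomyocyte proliferation and cardiac repair, and the single comparison implied by the labels is progesterone against vehicle.

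Progesterone libraries differed from control libraries in most of the expressed genes. Interferon-stimulated and inflammatory genes were lower with progesterone, and many were highly expressed in the controls and almost unread with progesterone. Genes of DNA replication and mitosis were higher with progesterone, as were mitochondrially encoded mRNAs, several matrix genes and markers of smooth muscle and of leukocytes. The calls of the interferon-stimulated and inflammatory lists hold with an estimated correlation, while those of the lists that rose do not (adjusted p from 0.070 for replication to 0.69 for leukocyte markers). Of 15075 genes tested with edgeR's quasi-likelihood test, 9497 changed at an adjusted p under 0.05, of which 4707 were higher and 4790 lower with progesterone. At least 2-fold changes were found for 1076 higher and 1404 lower genes, and at least 8-fold changes for 72 higher and 316 lower genes. The progesterone and control CPM values (counts scaled for library size) did not overlap in 10340 of the 15075 genes tested, where chance gives 10% for 3 against 3. Upper quartile scaling gave 60.1% of the changed genes as higher, against 49.6% with TMM scaling, and moved the median log2 fold change of all genes by 0.10.

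**Figure D1:**
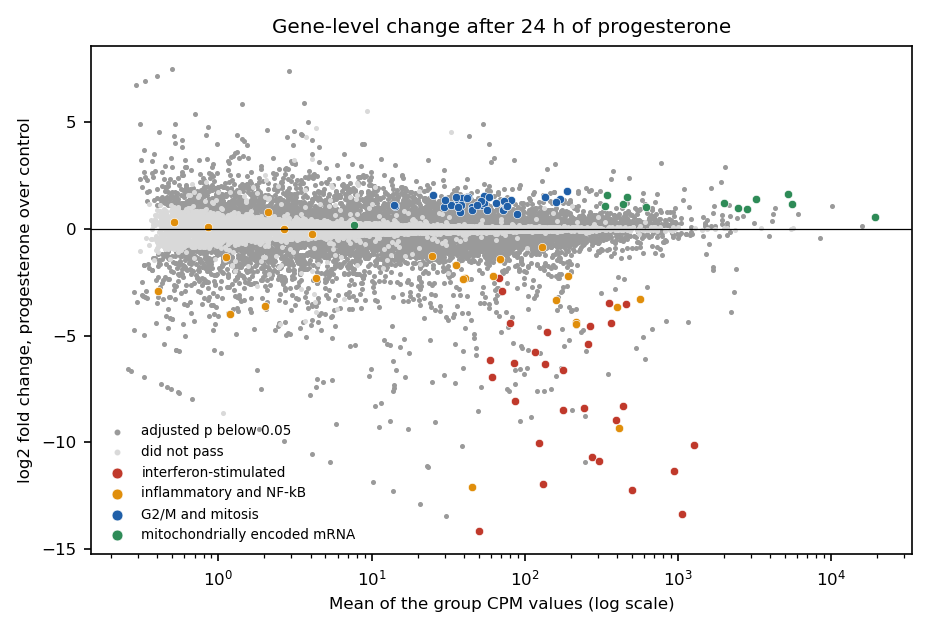
Each point is a gene tested, with the mean of the group CPM values on a log axis and the log2 fold change of progesterone over control on the vertical axis. Grey points passed an adjusted p of 0.05 and light grey points did not, and the coloured points are members of 4 lists. The interferon-stimulated genes lie from -2.29 down to -14.17, and the mitosis genes lie between 0.71 and 1.78.

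All 29 tested interferon-stimulated genes were lower with progesterone, with a median log2 fold change of -6.93 (adjusted p = 0.0014 with an estimated correlation between the genes). Mx1, an interferon-induced GTPase with antiviral activity, fell from 2136 ± 15.1 to 0.198 ± 0.0493 CPM (SD, n = 3), and Irf7, a transcription factor of the interferon response, from 2553 ± 43.3 to 2.28 ± 0.318 CPM. Ifit3 fell from 996 ± 18.1 to 0.199 ± 0.12 CPM and Rsad2, which encodes the antiviral enzyme viperin, from 613 ± 25 to 0.323 ± 0.0589 CPM. Gbp2 (log2 fold change -8.29 ± 0.06, SE), Gbp1 (-10.94 ± 0.24) and Oasl (-10.71 ± 0.08) fell as well. Oas2, an oligoadenylate synthetase, was read at 101 ± 5.45 CPM in the controls and had no count in any progesterone library, which makes it at least 2220-fold lower against a floor of 3 counts over the group. By the same floor Tmprss2 was at least 1350-fold lower, Rtp3 at least 917-fold and Ubd, which encodes a ubiquitin-like protein, at least 235-fold. Floors and counting intervals cover counting error only. The row of Tmprss2 on chromosome 11 (38063915 to 38103290, in a rat build that is not named) lies 3965 bases from that of Mx2 (38035450 to 38059950) on the opposite strand. The strand setting of the counting is not given in the sources used here, so reads from the pair may not be separable. Oas1a fell from 262 ± 4.6 to 0.0628 ± 0.109 CPM and Mx2 from 1895 ± 35.2 to 0.7 ± 0.519 CPM. Without progesterone replicate 2 the log2 fold change of Oas1a moved from -11.94 to -15.57, and without progesterone replicate 3 to -11.35, while that of Mx2 moved from -11.36 to -12.18 without progesterone replicate 3. Mx1 and Mx2, and the members of the Oas1, Ifit and Gbp families, are similar in sequence, and the counting could have divided reads between them.

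Among inflammatory cytokine and NF-kB target genes, 20 of 25 tested members were lower and none was higher, with a median log2 fold change of -2.29 (adjusted p = 0.021 with an estimated correlation). Ccl2 and Ccl7, which encode monocyte-attracting chemokines, fell from 1033 ± 61.1 to 105 ± 5.73 CPM and from 741 ± 31 to 59.7 ± 4.18 CPM. Cxcl10, a chemokine gene induced by interferon, fell from 824 ± 33.4 to 1.27 ± 0.409 CPM. Ccl5 had 6424 counts over the control libraries and 1 over the progesterone libraries, a ratio of 5936 (95% counting interval 1065 to 234495), and its log2 fold change moved from -12.08 to -14.02 without progesterone replicate 2. Klrk1, which encodes an activating receptor of lymphocytes, had 3287 and 1 counts, a ratio of 3037 (545 to 120003), and moved from -11.11 to -13.03 without progesterone replicate 3. The other list that fell was that of apoptosis regulators, with 15 of 23 lower and 4 higher, a median of -0.39 and an adjusted p of 0.025, but of 0.35 with an estimated correlation. Its leading members Birc3, an inhibitor of apoptosis that NF-kB induces, Bid and Casp8 had log2 fold changes of -3.47 ± 0.08, -1.69 ± 0.07 and -2.20 ± 0.13. Leukocyte markers, described below, moved the other way.

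Cell-cycle genes rose together. All 34 tested G2/M and mitosis genes were higher with progesterone, with a median log2 fold change of 1.22 and an adjusted p of 1.2e-27 with the preset correlation of 0.01, but of 0.15 with an estimated correlation. Of the 33 tested genes of the G1/S transition and DNA replication, 32 were higher and none was lower, with a median of 1.19 and adjusted p values of 5.4e-17 and, with an estimated correlation, 0.070. Mki67, a marker of cycling cells, rose from 93.3 ± 3.41 to 244 ± 7.97 CPM, Top2a from 85 ± 3.82 to 292 ± 4.42 CPM and Cdk1, the kinase that drives entry into mitosis, from 39.1 ± 5.11 to 90.8 ± 2.99 CPM. Anln and Prc1, which act in cytokinesis, rose 2.8-fold and 2.39-fold. The replication licensing genes Mcm6, Mcm5 and Mcm7 rose 2.83-fold, 3.46-fold and 2.44-fold, and Uhrf1 rose 3.47-fold. Cell cycle inhibitors and D-type cyclins moved both ways, with 7 of 20 higher and 9 lower and an adjusted p of 0.67. Ccnd1, which encodes cyclin D1, fell 1.24-fold, whereas Cdk4, its partner kinase, rose 1.49-fold. Of the ribosome biogenesis and MYC target genes, 23 of 28 were higher (median 0.40) and none was lower, or 1 lower adjusted over the list alone. Its adjusted p was 7.2e-05, and 0.45 with an estimated correlation. Cad, Nop56 and Nop58 rose 2.24-fold, 1.72-fold and 1.58-fold. Smooth muscle markers (median log2 fold change 1.05) and leukocyte markers (1.72) were higher in the same libraries as the cell-cycle genes.

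The targets of YAP and its TEAD partners, the question in the series title, moved in both directions. Of 31 tested, 17 were higher and 9 lower, with a median log2 fold change of 0.31 and an adjusted p of 0.028, or 0.61 with an estimated correlation. Ccn1 and Ccn2, secreted matricellular proteins, rose 3.3-fold and 3.72-fold, from 72.1 ± 13.8 to 238 ± 10.4 CPM and from 463 ± 49.1 to 1721 ± 133 CPM. Ankrd1 rose 1.33-fold, Thbs1 2.55-fold and Tgfb2 2.59-fold, whereas Igfbp3 fell 4.74-fold and Axl 1.92-fold. Several of these are on other lists too. Ccn2 and Thbs1 are on the matrix list, Ccn1 on the immediate early list and Ankrd1 on the fetal cardiac list. Tgfb2 and Igfbp3 are on the growth factor list, so these changes do not single out YAP. Amotl2 had a log2 fold change of -0.09 ± 0.06 and did not pass (adjusted p = 0.21), although it passed without progesterone replicate 1 (-0.15, adjusted p = 0.032). Yap1 itself rose from 66.2 ± 5.57 to 96.8 ± 2.3 CPM, while Wwtr1, which encodes the related coactivator TAZ, fell from 69.1 ± 1.86 to 55.9 ± 0.522 CPM. Of 21 tested Hippo pathway components, 9 were higher and 7 lower (adjusted p = 0.31), with Fat4, a giant cadherin, at a log2 fold change of 1.93 ± 0.10.

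Steroid receptor genes and genes induced through the progesterone or glucocorticoid receptor were mostly lower or mixed. Of 12 tested nuclear and membrane steroid receptor genes, 10 were lower and 1 was higher (median log2 fold change -0.48), without an adjusted list p under 0.05 (0.31, but 0.040 without a filter and 0.039 without mitochondrial and at least 4-fold lowered genes). Pgrmc1, a membrane-associated progesterone receptor component, fell from 170 ± 2.81 to 116 ± 2.52 CPM, and Nr3c1, the glucocorticoid receptor, from 143 ± 4.82 to 117 ± 3.94 CPM. Pgr, the nuclear progesterone receptor, was too low to be tested, with 1 count over the 3 control libraries and 14 over the 3 progesterone libraries. Of 26 tested genes induced through either receptor, 8 were higher and 12 lower, or 13 lower adjusted over the list alone, and the list p was 0.11 after adjustment. The list passed without progesterone replicate 3 (adjusted p = 0.024) and with a replicate block (0.0031). Fkbp5 and Tsc22d3, which are commonly induced by glucocorticoids and progestins, fell 1.3-fold and 1.27-fold. Nfkbia and Glul fell 4.64-fold and 3.98-fold, while Tgm2 rose 1.96-fold. Nfkbia is also on the inflammatory and NF-kB list, where 20 of 25 members were lower, so its fall does not single out these receptors.

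**Figure D2:**
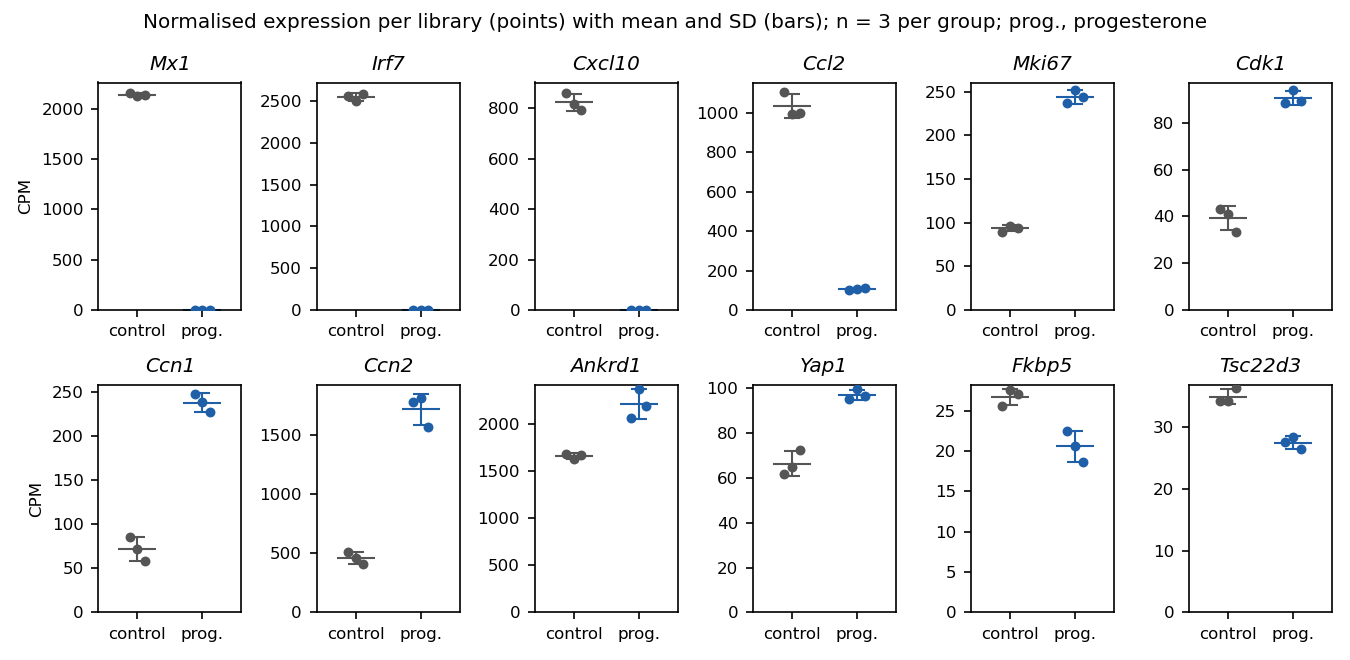
CPM of 12 named genes in each library, with points for libraries and bars for the mean and SD of 3 control and 3 progesterone libraries; every vertical axis starts at 0. Mx1, Irf7, Cxcl10, Ccl2, Fkbp5 and Tsc22d3 lie lower with progesterone, and Mki67, Cdk1, Ccn1, Ccn2, Ankrd1 and Yap1 higher.

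Adult sarcomere genes moved both ways, and most fetal and stress-related cardiac genes were higher. Of 24 tested adult sarcomere and Z-disc genes, 7 were higher and 9 lower, with a median log2 fold change of -0.00 and an adjusted p of 0.67. The mean of the list was -0.02 and the direction of its list test was up, so that the signs differ. Myh6, the adult rodent myosin heavy chain, fell from 4384 ± 270 to 3498 ± 220 CPM and Tnnt2 from 2307 ± 28.4 to 1881 ± 120 CPM, while Actc1 rose from 4627 ± 202 to 7514 ± 760 CPM. Of 17 fetal and stress-related cardiac genes, 15 were higher and 2 lower (median 0.55), with an adjusted p of 0.00035, and of 0.59 with an estimated correlation. Acta2, Tagln, Cnn1 and Des are also on the smooth muscle and pericyte list (median 1.05), so the list does not show which cells the rise comes from. Nppa and Nppb, the natriuretic peptide genes, rose 1.32-fold and 1.56-fold, Acta1 3.49-fold and Vim 2.16-fold. Myh7 rose 1.1-fold (adjusted p = 0.012), a call that was lost without progesterone replicate 2 (adjusted p = 0.057). Ion channel and calcium handling genes moved both ways, with 12 of 26 higher and 10 lower (adjusted p = 0.67; median 0.09, mean -0.03). Gja1, connexin 43, fell 1.58-fold, while Jph2 rose 1.41-fold.

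Among the lists of energy metabolism, that of oxidative phosphorylation passed, though not with an estimated correlation. All 17 of the 24 fatty acid uptake and oxidation genes that changed were lower (median log2 fold change -0.32), but the list did not pass (adjusted p = 0.084). It passed without control replicate 1 (adjusted p = 0.032) or 3 (0.0087), with a replicate block (0.035), without a filter (0.00012) and without mitochondrial and at least 4-fold lowered genes (0.00094). Ppard and Eci1 fell 1.81-fold and 1.9-fold. Of 39 nuclear-encoded oxidative phosphorylation genes, 28 were higher and 1 lower, or 2 lower adjusted over the list alone, with a median of 0.18, an adjusted p of 0.029 and 0.69 with an estimated correlation. Cyc1, a subunit of complex III, rose 1.35-fold. Glycolysis and hypoxia genes had 5 of 28 higher and 12 lower (adjusted p = 0.58). Slc2a4, the insulin-responsive glucose transporter, was 2.02-fold lower and Ca9 3.85-fold higher (from 3.1 to 12 CPM). Cholesterol biosynthesis genes had 9 of 28 higher and 7 lower (adjusted p = 0.72; median 0.02, mean -0.04). Of 12 LXR target and cholesterol efflux genes, 10 were lower and 2 higher (adjusted p = 0.42, and 0.017 without a filter), with Abca1, a cholesterol exporter, 2.36-fold higher.

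Mitochondrially encoded mRNAs rose, and mitochondrial rRNAs fell. Of 13 tested mitochondrial mRNAs, 12 were higher and none was lower, with a median log2 fold change of 1.17, an adjusted p of 6.3e-14 and 0.13 with an estimated correlation. Mt-cyb rose from 2542 ± 89.4 to 7990 ± 121 CPM and Mt-atp6 from 1767 ± 31.3 to 4722 ± 129 CPM. Mitochondrial mRNAs made up 2.94% ± 0.0403 of the control counts and 5.61% ± 0.131 of the progesterone counts, while mitochondrial rRNAs made up 0.789% ± 0.0189 and 0.156% ± 0.0137 (SD, n = 3). The 2 mitochondrial rRNA rows had log2 fold changes of -1.86 and -2.94. Cytoplasmic ribosomal protein genes were higher in 29 of 35 members and lower in none (median 0.30), with an adjusted p of 0.0060 and 0.69 with an estimated correlation, and Rpl7 rose 1.36-fold. Of 7 tested replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, 1 was higher and 3 were lower (adjusted p = 0.87).

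Matrix genes were mostly higher, and growth factor genes moved both ways. Of 36 extracellular matrix and TGF-beta responsive genes, 25 were higher and 5 lower (median log2 fold change 0.52), with an adjusted p of 1.7e-08 and 0.25 with an estimated correlation. In the same libraries 15 of 18 smooth muscle and pericyte markers (median 1.05) and 11 of 19 fibroblast markers (median 0.52) were higher. Col6a3, a collagen VI chain, rose from 483 ± 9.85 to 3602 ± 300 CPM, Eln, elastin, from 683 ± 11 to 3149 ± 281 CPM and Tnc, tenascin C, from 152 ± 11.8 to 811 ± 31.9 CPM. Of 35 growth factor and receptor genes of the heart, 16 were higher and 14 lower (adjusted p = 0.34). Igf2, an imprinted growth factor gene, rose from 33.8 ± 0.809 to 282 ± 14.6 CPM, whereas Agrn, agrin, fell from 320 ± 8.75 to 83.1 ± 1.03 CPM.

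Markers of other cell types moved apart. Smooth muscle and pericyte markers were higher in 15 of 18 members and lower in 3, with a median log2 fold change of 1.05 and an adjusted p of 3.5e-06, or 0.13 with an estimated correlation. Itga8 and Mylk rose 3.77-fold and 2.14-fold. Leukocyte markers were higher in 13 of 15 members and lower in 1, with a median of 1.72, an adjusted p of 0.029 and 0.69 with an estimated correlation, and the call was lost with upper quartile scaling (adjusted p = 0.060). Csf1r, the receptor of macrophage growth factor, rose from 3.29 ± 1.1 to 16.2 ± 1.39 CPM, while Cd74, the MHC class II chaperone, fell from 12.6 ± 1.52 to 1.63 ± 0.545 CPM. Fibroblast markers were higher in 11 of 19 members and lower in 5 (median 0.52, adjusted p = 0.17, and 0.040 without a filter), with Col3a1 2.09-fold higher and Ddr2 1.62-fold lower. Col3a1, at 6556 CPM in the controls and 13735 CPM with progesterone, was read more than Myh6, at 4384 and 3498 CPM. Endothelial markers were higher in 5 of 17 and lower in 7, or 8 adjusted over the list alone (median -0.33, adjusted p = 0.77), with Tek 3.6-fold lower and Flt1 2.05-fold higher. Epicardial and mesothelial markers had 5 of 12 higher, or 6 adjusted over the list alone, and 5 lower (adjusted p = 0.58). Schwann cell and neuron markers had 4 of 10 higher and 3 lower (adjusted p = 0.58), and of 4 tested erythroid and platelet markers, too few for a list test, 1 was higher and 2 were lower.

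The lists of immediate early, heat shock, endoplasmic reticulum stress and p53 target genes did not pass. Immediate early genes were higher in 13 of 23 members and lower in 5 (adjusted p = 0.38), with Egr1 1.74-fold lower and Egr2 2.63-fold higher. Heat shock and chaperone genes had 6 of 21 higher and 7 lower (adjusted p = 0.58; median 0.00, mean -0.12), with Hsph1 2.33-fold lower. Endoplasmic reticulum stress and amino acid response genes had 11 of 30 higher and 7 lower (adjusted p = 0.67), with Ddit3, which encodes the stress-induced factor CHOP, 6.06-fold lower. Targets of p53 had 10 of 22 higher and 5 lower (adjusted p = 0.42), with Sesn2 1.62-fold higher and Perp 1.54-fold lower.

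**Figure D3:**
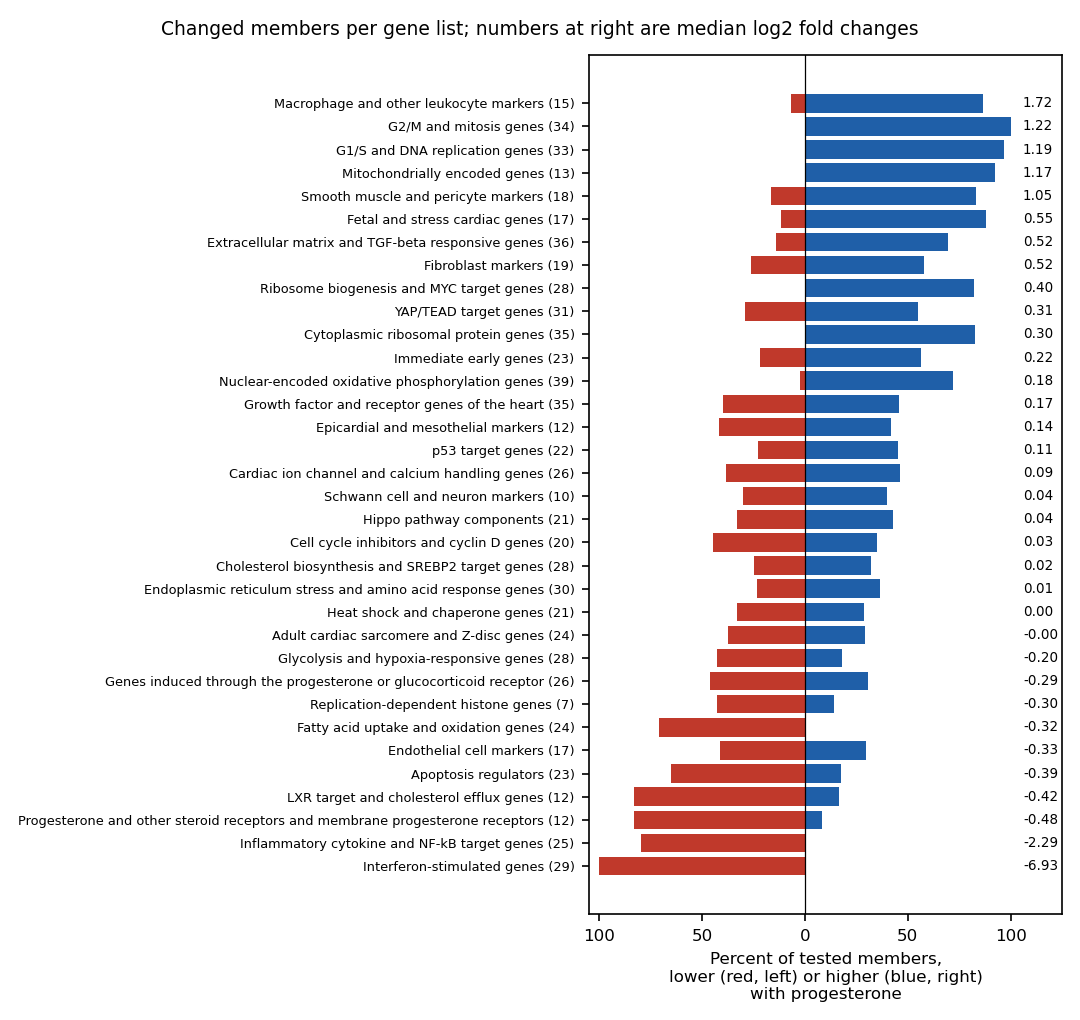
Percent of the tested members of each list (number in parentheses) that were lower (red, left) or higher (blue, right) with progesterone at an adjusted p under 0.05; the rest did not pass. Numbers at the right are median log2 fold changes, from 1.72 for leukocyte markers to -6.93 for interferon-stimulated genes.

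The named genes with the largest increases included several that were nearly unread in the controls. Acan, aggrecan, rose from 3.4 ± 0.258 to 104 ± 5.36 CPM, and Myh3, embryonic skeletal myosin, from 1.01 ± 0.439 to 16.4 ± 2.83 CPM. Wscd2 rose 15.8-fold, Tgm3 19.7-fold and Adamts16 24.7-fold. Cyp1a1, a target of the aryl hydrocarbon receptor, rose from 0.112 ± 0.0663 to 7.09 ± 1.3 CPM, and Myh2, fast skeletal myosin, from 0.152 ± 0.132 to 3.99 ± 0.407 CPM. Epha8 had 2 and 377 counts over the groups, a ratio of 204 (95% counting interval 56.1 to 1691), and Dmrt2 had 3 and 183 counts, a ratio of 66 (22.2 to 323). The log2 fold change of Dmrt2 moved from 5.88 to 6.74 without control replicate 2, and that of Lilrb3, a leukocyte receptor gene, from 4.42 to 5.14 without control replicate 3. The Mir675 row, 84 bases long and inside the H19 precursor, rose from 4.07 ± 0.524 to 82.8 ± 4.42 CPM, a value from reads of mRNA-enriched libraries rather than of mature microRNA. Ndufa1, a complex I subunit gene, was read at 0.221 ± 0.157 and 7.52 ± 8.83 CPM, and its call (adjusted p = 0.039) was lost without control replicate 1, 2 or 3 (adjusted p = 0.11, 0.11 and 0.12) or progesterone replicate 3 (0.052), and without a filter (0.059). Without progesterone replicate 2 its log2 fold change was 3.42 in place of 5.04.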

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

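One of these alternatives, that without genes lower by 4-fold or more and without mitochondrial genes, was chosen after seeing the data. The count of changed genes, 9497, was 9499 with RLE, 9722 with upper quartile and 9452 with library size scaling, 9871 without a filter, 9136 with the stricter filter, 8702 with DESeq2, 9373 and 9321 on log2 FPKM, 8893 in the added setting and between 8686 and 9131 with a replicate left out. It was 2480 with at least a 2-fold change and 7886 at an adjusted p under 0.01. No gene called both in the reported test and in an alternative had the opposite sign. Of 174 named genes, 169 kept their direction and their side of the threshold in the alternatives run on them, 16 for 143 genes and 15 for 31, of which the added setting leaves out 30 and the stricter filter C1qc. The exceptions were Ndufa1, Amotl2, Myh7, Hba-a2 (adjusted p = 0.022 without control replicate 3) and Hist1h1b (0.090 without control replicate 2 and 0.056 without progesterone replicate 3), and the cause was not tested. Of the 34 list tests, 14 were called, against 2 with an estimated correlation and 26 with fry, which asks whether a list moves on balance and does not compare it with other genes. With a replicate left out, 14 to 15 lists were called, with upper quartile scaling 13, without a filter 18, and 14 in the added setting, which gained fatty acid oxidation (adjusted p = 0.00094) and steroid receptors (0.039) and leaves out the interferon and mitochondrial lists. The lowest correlation between replicates was 0.988 by Pearson and 0.994 by Spearman. In simulated counts 60% of genes changed 1.5-fold and 90% of those changed 2-fold were recovered. Only 50 genes changed at each simulated fold, which gave 154 calls, against 9497 in the data. With fewer calls the adjustment is stricter, so these shares do not measure how completely small changes are covered in the data.

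No pairing by replicate number was seen, as same-numbered deviations correlated at 0.0492, 0.018 and -0.000936, but these values do not exclude one. With the number as a replicate block 9508 genes and 16 lists were called.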

Other observations

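Further groups that moved were looked at with 5 lists chosen after the data were seen, in part from genes that had moved, so their list p-values are left out. All 19 tested genes of MHC class I, peptide loading and the immunoproteasome were lower with progesterone (median log2 fold change -3.94). B2m, the invariant chain of MHC class I, fell from 4139 to 276 CPM. Of 14 tested RNA and DNA sensing genes, 12 were lower and 1 higher (median -2.33). Of 11 imprinted and fetal growth genes, 7 were higher and 2 lower (median 0.44), led by Igf2. Of 5 skeletal muscle genes, 4 were higher (median 2.26), and of 6 aryl hydrocarbon receptor targets, 3 were higher and 2 lower (median 0.43).

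The tests on transcript length, on the lists without strongly lowered genes and on splits of the libraries were set before their results were seen, and all others below were chosen after. The test on other differences between the cultures replaced an earlier one after its value was seen. The earlier test, the larger within-group range of the mean log2 CPM of the interferon list (0.211, against a group difference of -7.36), decided nothing either and could not have excluded the explanation. After their values were seen, the bound of the test on poly(A) tails was made stricter, the p in place of the median was read from the test on strongly lowered genes, and the explanation on macrophages was narrowed from all leukocytes.

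Interferon-stimulated genes were lower with progesterone than in each of the 3 control libraries, with a median log2 fold change of -6.93. More macrophages in the controls are argued against by the macrophage and other leukocyte markers, of which 13 of 15 were higher with progesterone (median log2 fold change 1.72), but Cd74 (-2.95) and Klrk1 (-11.11) were lower, and more lymphocytes in the controls stay open. Type I interferon made in the control cultures is a candidate explanation, as Ifnb1 had 17 counts there and 0 with progesterone, but the counts are few and the p of 1.47e-05 (one-sided exact conditional test) covers counting error only. A difference between the cultures other than progesterone cannot be told apart from the treatment, because no label names the cultures. The marker lists of other cell types moved by up to 1.72, but the treatment could have moved them as well, so they decide nothing. Suppression by progesterone of a response present in the controls stays open as well.

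Mitochondrial mRNAs were higher and mitochondrial rRNAs lower with progesterone. More mitochondrial RNA of every kind is not decided. The less reduced rRNA row had a log2 fold change of -1.86, but that fall is part of the pattern to be explained. The libraries were mRNA-enriched, so rRNA reads also depend on how well RNAs without a poly(A) tail were removed. A transcript length bias is argued against, since the mRNAs stayed at a median of 1.14 relative to nuclear genes of like length. Poorer removal of RNAs without a poly(A) tail from the controls stays open, since the median of 116 small nuclear, nucleolar and similar RNAs was 0.42, but 3 of 7 histone mRNAs were lower and 1 higher (median -0.30), and 3 of 8 mitochondrial tRNAs were lower and 3 higher (median -0.14). A change in mitochondrial transcription or RNA turnover may be involved and was not tested.

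Mitosis and replication genes were higher with progesterone. A smaller share of cardiomyocytes with all other cell types alike is not decided by the marker lists. Adult sarcomere genes, which a smaller share would lower, had a median of -0.00015, with 7 of 24 higher and 9 lower. Their expression per cell could have changed too, so these values do not measure the share. Smooth muscle (median 1.05) and endothelial markers (-0.33) differed in median (two-sided permutation p = 0.00035 over genes). That p treats the genes as independent and does not cover the spread between cultures. The estimated correlation among endothelial markers was 0.71, and 5 of them were higher and 7 lower. More dividing smooth muscle-like, fibroblast or leukocyte cells cannot be told apart from dividing cardiomyocytes in bulk libraries, since their marker medians, up to 1.72, lie on both sides of that of the mitosis genes. Without the 579 mitochondrial and strongly lowered genes the call of the mitosis genes stayed (adjusted p = 5.8e-49 by camera with the preset correlation, median 1.20). With all genes and an estimated correlation it is lost (adjusted p = 0.15). All 34 mitosis genes were higher by themselves, and the genes left out were picked from the same fit. The call could hardly have been lost, so its staying does not show what set it. Of the 10 splits of the 6 libraries, 1, the real one, gave as many genes (9497, against at most 0 in the others), and 10 splits are too few for a share under 0.05. The other splits mix control and progesterone libraries, so the group difference counts as spread and a low number of calls was set in advance.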
